A study of Homo sapiens with 6 samples.

How the data were processed

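Poly(A) RNA of HBEC3kt cells was reverse transcribed by the Smart-Seq2 approach from a poly(A) primer and read on a MinION with 1D nanopore chemistry, per the labels' protocols. The 6 libraries hold 3 wild-type and 3 U2AF1 S34F samples, and genotypes and replicate numbers were taken from the labels. The source names give 2 isolates per genotype, with isolate 2 read again as replicate 3, and the titles mark replicates 1 and 2 as B1 and replicate 3 as B2. What B1 and B2 stand for, and how the isolates were derived, is not given in the sources used here.

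The deposited table holds the raw count of long reads per isoform and library, made by the authors over a single isoform set of the whole series, which the name of the isoform file ties to the tool FLAIR. The values are whole numbers and no normalization was found in them. The build is hg19 per the submitters' processing notes. Aligner, versions, filters, how reads were assigned to isoforms and whether strand was used are not given in the sources used here. The deposited isoform models gave exon positions, and their CDS records were not used here, since in 42259 of 63289 models they equal the exons. Of the models, 65 have no counts. Every sample column was used.

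Counts were summed per gene, with 49002 isoforms in 11034 Ensembl genes and 14222 isoforms at 13186 loci without a gene ID. Symbols for 10859 of the Ensembl IDs came from a GENCODE annotation given for another build. Its coordinates were used only to read the base before the AG, as described below. Library totals ranged from 451540 to 1720292 reads with means of 1530324 in wild-type and 759221 in S34F libraries, so a gene at 10 CPM has few reads in the shallowest library. Splicing events were built from the exon chains of the isoforms of each gene. They were 12126 cassette exons, 3672 alternative 5′ splice sites, 4666 alternative 3′ splice sites and 4240 retained introns. For each event, the reads of isoforms with and without the form were counted in every library. For alternative splice sites, the longer form took all isoforms using the site that can lengthen the exon, also those ending before the other site. The 3′ ends of a gene were merged within 100 bases and the 2 ends with most reads compared.

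Gene and isoform counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, the filter filterByExpr (at least 10 reads, 15 in total) and a term for B1/B2. The Benjamini-Hochberg adjusted p was held to 0.05. This leaves 3 residual degrees of freedom. Isoform usage was tested with edgeR's diffSpliceDGE and Simes p-values per gene. Events and 3′ ends with at least 10 informative reads in every library were tested with an edgeR model on 2 counts per library, with library terms. In that model the prior degrees of freedom came out infinite, so every event shares 1 trended spread, while limma 3.58.1 on log odds (offset 0.5) estimated 3.49 for events and 2.98 for ends. Gene lists were tested with camera of limma at a preset correlation of 0.01, and with an estimated correlation and fry beside it, over 22 lists. The lists of long noncoding genes and of loci without a gene ID were added after the data were seen. DESeq2 1.42.0 and limma-voom were run as alternatives, and counting and event building used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots matplotlib 3.10.9. An adjusted p that DESeq2 left empty was kept out of counts of lost calls.

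The base before the AG of a 3′ splice site was planned to be read from the genome of the build, which was not at hand. It was read instead, by a route chosen after the data were seen, from GENCODE transcripts that share the exon by transcript ID, exon order and lengths and where an exon of another transcript covers the end of the intron. This gave a base for 2857 of the 12126 cassette exons (23.6%), of which 2853 were followed by AG. Both tests of this base were fixed before the data were examined: inclusion pooled per library with an exact test of 3 against 3, put first in the plan, and a permutation across exons with equal weight. The larger difference and the small p come from the permutation across exons, while the pooled comparison, at 3 against 3 libraries, could not pass the threshold. These exons are a selected part, as an annotated transcript must run through the intron end.

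Named genes were chosen by a rule. At gene level it takes the 12 largest rises and the 12 largest falls among called genes whose ranges do not overlap between the genotypes, and at isoform level 6 and 6. It takes the 12 genes with the smallest adjusted p in isoform usage, the 6 events of each type and the 6 3′ ends with the smallest adjusted p. It always takes U2AF1 and the measured genes of a list of splicing targets of the mutation named before, and per gene list 2 to 4 members with the smallest p. Genes named outside it are marked as chosen after their values were seen. The rule, the tests, the gene lists other than the 2 added and most alternatives were fixed before the data were examined.

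Equal replicate numbers in both genotypes were checked for pairing by the correlation of the libraries' deviations from their genotype means across genes. It was 0.480, 0.149 and 0.837 for replicates 1, 2 and 3. Unlike numbers within B1 correlated more, at 0.526 for wild-type replicate 2 with S34F replicate 1 and 0.307 for wild-type replicate 1 with S34F replicate 2. The libraries thus pair by B1 and B2 and not by number within B1. There the correlation of the differences between replicates 1 and 2 was -0.0707. A fit with the number as a replicate block was run as an alternative for genes (187 in place of 228), isoforms, usage, events, 3′ ends and gene lists. It was not run for the base before the AG or for the make-up of the libraries. Scaling moved the median log2 fold change of all genes little: it was 0.02 with TMM, 0.04 with DESeq2-type factors and -0.06 unscaled. Replicates of a genotype differed by more than counting error, with a chi-square per degree of freedom of 4.13 to 22.0.

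The tests were tried on simulated data with known answers, drawn from the means and depths of these libraries. At gene level 27% of genes changed 2-fold and 85% of those changed 4-fold were recovered, and 10.4% of calls were false among 6486 tested genes. For isoforms these were 9%, 77% and 1.15% among 12318. For isoform usage 48% of genes with their 2 main isoforms swapped were recovered among 2040, with 8.57% false calls. For events 40.5% of those shifted by 2 in log2 odds were recovered among 15567, with 3.57% false calls, and for 3′ ends 43% among 2370, with 12.2% false calls, at the overdispersion fitted to the data (0.00474 and 0.0116). At an overdispersion of 0.02 assumed at first, 0 of 200 were recovered in both. The false shares above 5% stand at gene, usage and 3′ end level.

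Alternatives comprised DESeq2-type size factors, other filters, DESeq2, limma-voom, a minimum change, no B1/B2 term, the replicate block, summed libraries of isolate 2, B1 libraries alone, each library left out in turn and, added after the data were seen, all libraries thinned to 451540 reads. Shares of exons or introns that were higher or lower carry exact binomial 95% intervals where given. These treat exons and introns as independent, though those of a gene can share reads. Ratios with 1 to 3 reads in a genotype carry counting intervals. Raw reads, reading frames and base calls were not analysed here.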

Results

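Full-length cDNA of HBEC3kt cells, a line of bronchial epithelial cells immortalised in culture, was read by nanopore sequencing in 6 libraries. The 3 wild-type and 3 U2AF1 S34F libraries come from 2 isolates per genotype. Replicates 1 and 2 of each genotype are isolates 1 and 2 in libraries marked B1, and replicate 3 is isolate 2 again in a library marked B2. U2AF1 encodes the small subunit of U2AF, which contacts the AG at the end of introns, and S34F replaces a serine of that subunit with phenylalanine. The comparison asks how RNA processing and transcript levels differ between cells with and without this mutation. Replicates 1, 2 and 3 held 1720292, 1286512 and 1584167 assigned reads in wild-type cells and 811255, 451540 and 1014868 in S34F cells. The 6868634 reads fell on 63224 isoforms, of which 16390 carried an annotated transcript ID and 14222 lay at loci without a gene ID. Reads at such loci made up 17.5% to 19% of both B2 libraries and 8.22% to 9.86% of the B1 libraries. The B2 libraries also stood apart on the first principal component of gene levels (52.3% of the variance), while the genotypes parted on the second (22.6%). Positions are in build hg19, values are means ± SD of 3 libraries (n = 3), and levels are TMM-scaled CPM.

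U2AF1, the mutated gene (ENSG00000160201.7, chromosome 21, 44513067 to 44527675), was read at 457 ± 138 CPM in wild-type and 399 ± 148 CPM in S34F libraries. Its level was not called different (log2 fold change -0.22, edgeR adjusted p = 0.764 after Benjamini-Hochberg correction). Counts carry no base calls that could check the genotype labels. Inflammatory mediators were among the genes that fell in S34F cells. IL1B (ENSG00000125538.7, chromosome 2, 113587329 to 113594354), the gene of the cytokine interleukin 1 beta, fell from 343 ± 14.3 to 21.0 ± 6.96 CPM (log2 fold change -4.03, SE 0.33, edgeR adjusted p = 2.07e-05). ALOX5AP (chromosome 13, 31309390 to 31339194), whose product hands arachidonic acid to 5-lipoxygenase for leukotriene synthesis, fell from 211 ± 92.1 to 4.09 ± 0.732 CPM (log2 fold change -5.60, edgeR adjusted p = 2.07e-05). The neutrophil-attracting chemokine gene CXCL2 fell from 97.2 ± 18.7 to 1.97 ± 1.89 CPM, a log2 fold change of -5.43. Its close paralogues CXCL3 and CXCL1, between which long reads may be shared, were read 256 and 101 times in wild-type libraries and 3 times and 1 time in S34F libraries. After scaling for depth, wild-type levels were 40.2 times (95% counting interval 13.6 to 196) those of S34F cells for CXCL3 and 47.6 times (8.35 to 1898) for CXCL1. The collagenase gene MMP1 had 241 reads against 1 (ratio 114, 20.2 to 4503), and IL1RL1, which encodes the receptor of interleukin 33, had 170 against 1 (ratio 80.1, 14.2 to 3182). These intervals cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

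Other large falls were those of MAP1B, a microtubule-associated protein gene (72.8 ± 45.6 to 2.75 ± 3.27 CPM, log2 fold change -4.99), and of STC2, which encodes the secreted glycoprotein stanniocalcin 2 (272 ± 73.0 to 20.2 ± 13.1 CPM, log2 fold change -3.88). ICA1, with 93 reads against 1 (ratio 43.8, 7.67 to 1749), and the antisense gene LURAP1L-AS1, with 71 against 1 (ratio 33.5, 5.81 to 1340), fell as well. The counting is not stated to use strand, so LURAP1L-AS1 cannot be told apart from its partner on the other strand. A locus without a gene ID beside STC2 (chromosome 5, 172741717 to 172742945) fell from 115 reads to 2 (ratio 27.1, 7.33 to 226). UPP1 (ENSG00000183696.9, chromosome 7, 48128226 to 48148314), which encodes uridine phosphorylase 1, fell from 1162 ± 381 to 143 ± 43.0 CPM (log2 fold change -3.01, edgeR adjusted p = 0.000121). The ligands of the epidermal growth factor receptor HBEGF (182 ± 113 to 18.2 ± 13.7 CPM), AREG (906 ± 144 to 173 ± 19 CPM) and EREG (23.3 ± 6.04 to 2.51 ± 1.12 CPM) also fell, and were chosen after their values were seen.

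Rises in S34F cells were fewer. A locus without a gene ID on chromosome X (86978928 to 86983679) had 41 S34F reads and 0 wild-type reads, at least 29-fold higher against a floor of 3 reads over the group. AEBP1, a gene of the extracellular matrix, had 33 S34F reads and 1 wild-type read (ratio 70.0, 11.7 to 2849). Loci on chromosome 18 (26736822 to 26754177), chromosome 10 (105342800 to 105343489), chromosome 1 (183170908 to 183171371) and chromosome 13 (82264385 to 82265207) rose with log2 fold changes of 4.72, 2.79, 2.58 and 2.48. GSTM3, a glutathione transferase gene, rose from 5.83 ± 1.02 to 55.9 ± 30 CPM (log2 fold change 3.22), and AKR1C3, an aldo-keto reductase gene, from 8.81 ± 3.19 to 54.4 ± 0.714 CPM (log2 fold change 2.61). Both belong to families of similar genes that can share reads, and AKR1C2 rose as well (log2 fold change 2.13), which was named after its value was seen. The nuclear receptor gene NR2F2 (log2 fold change 2.42), the replication licensing gene CDC6 (2.38), CCDC28B (2.32) and the small heat-shock protein gene HSPB1 (2.30, 137 ± 26.4 to 844 ± 866 CPM) completed the 12 largest rises.

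**Figure D1:**
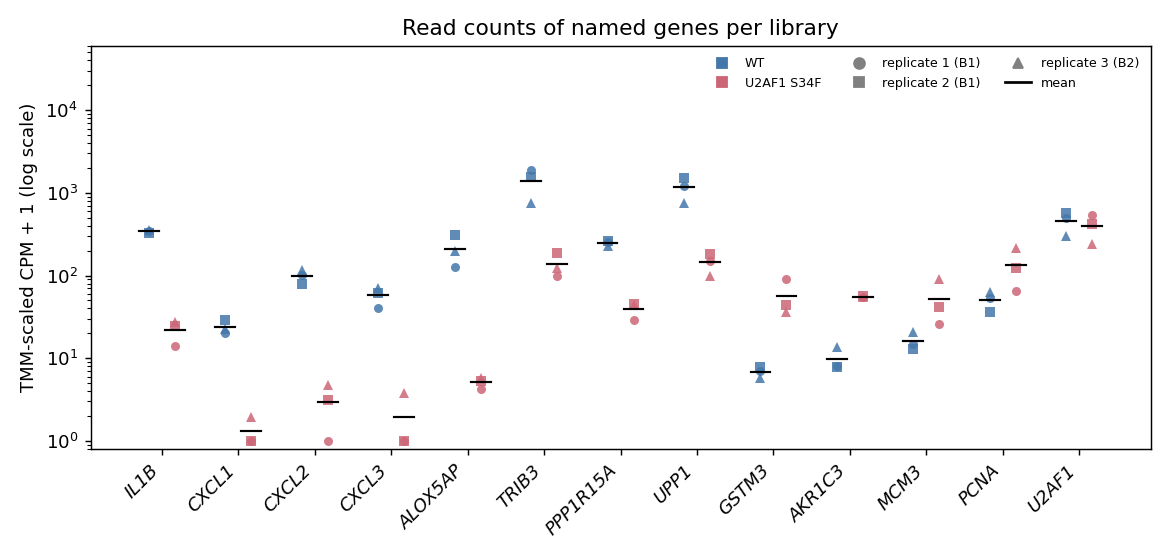
Level of 13 genes in each library as TMM-scaled CPM plus 1 on a log axis, with 1 point per library, the shape giving the replicate and the bar the mean of 3 libraries. IL1B lies near 343 CPM in wild-type and 21.0 CPM in S34F libraries, while U2AF1 overlaps between the genotypes (457 and 399 CPM).

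In all, 228 of 7033 tested genes and loci passed an adjusted p of 0.05 (edgeR quasi-likelihood test with B1/B2 as a term, Benjamini-Hochberg), 78 higher and 150 lower in S34F cells. They include 168 of 5621 protein-coding genes (58 higher, 110 lower), 5 lower lincRNA genes and 1 higher of 52, and 7 of 41 antisense genes, each of them lower, though without stated strand their reads cannot be told apart from those of genes on the other strand. Across all 7033 tested genes, which are not independent replicates, the direction was the same in B1 and B2 for 4911 (69.8%), and the log2 fold changes of B1 and B2 correlated with r = 0.614. The p-values measure only the spread between these libraries. The count was 2 without the B1/B2 term, and edgeR called 0 (287 at an unadjusted p under 0.05) when the libraries of isolate 2 were summed, leaving 2 samples per genotype. Leaving out wild-type replicate 1, 2 or 3 gave 110, 68 or 67 genes, and leaving out S34F replicate 1, 2 or 3 gave 519, 655 or 94. B1 libraries alone gave 79, equal depth 87, a minimum of 10 reads in every library 72 and no filter 491.

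Of the 24 largest changes and UPP1, 16 were called whichever library was left out. The others follow with their edgeR adjusted p after Benjamini-Hochberg correction. NR2F2 was not called without wild-type replicate 1, 2 or 3 (0.0764, 0.162 and 0.121) or S34F replicate 1 or 3 (0.0528 and 0.0958). The chromosome 13 locus was not called without wild-type replicate 1, 2 or 3 (0.0680, 0.220 and 0.194) or S34F replicate 3 (0.183). CCDC28B was not called without wild-type replicate 1, 2 or 3 (0.0757, 0.0658 and 0.0869). CDC6 was not called without wild-type replicate 2 or 3 (0.0560 and 0.127) or S34F replicate 3 (0.124), nor HSPB1 without wild-type replicate 1 or 2 (0.171 and 0.234). Wild-type replicate 3 alone decided ICA1 (0.0699), the chromosome 1 locus (0.0586) and the locus beside STC2 (0.0732), and S34F replicate 3 decided LURAP1L-AS1 (0.0552).

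Among 15 measured inflammatory cytokine and chemokine genes, 10 were tested and 8 fell in S34F cells: IL1B, CXCL1, CXCL2, CXCL3, IL32 (log2 fold change -2.47), IL1A (-2.45), CSF3 (-3.16) and CCL20 (-3.83). IL18 had a log2 fold change of 0.90 and NFKBIA of -0.23, neither called. Of the tested members, 9 passed when adjusted over the list alone, 8 lower and IL18 higher. The list was lower as a set (median log2 fold change -3.49, camera adjusted p = 5.44e-24 after Benjamini-Hochberg correction over 22 lists), with adjusted p = 0.220 with an estimated correlation. It was the only list called by limma's fry (adjusted p = 0.0424), a test of whether members move one way on balance. Without the B1/B2 term 1 member was called, and at equal depth 4 of 7 tested.

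Of 20 measured genes of the unfolded protein response, 17 were tested and 5 fell. These 5 are known as targets of the stress factor ATF4 or its partners: TRIB3 (1397 ± 590 to 135 ± 44.6 CPM, log2 fold change -3.27), PPP1R15A (247 ± 17.6 to 38.3 ± 9.08 CPM, -2.68), DDIT3 (-1.73), SESN2 (-1.75) and CHAC1 (-2.0). Chaperone and co-chaperone genes of the endoplasmic reticulum in the list were not called among all genes: HSPA5 had a log2 fold change of -0.24, CALR of 0.26, HSP90B1 of 0.68 and DNAJB9 of -1.62, the last passing when adjusted over the list alone (0.0195). The list was lower (median -0.73, camera adjusted p = 2.68e-06; adjusted p = 0.220 with an estimated correlation), with 9 lower members adjusted over the list alone. The count of 5 was 3 without wild-type replicate 2, 2 without wild-type replicate 3 or S34F replicate 3, 8 without S34F replicate 1 or 2, 2 in B1 libraries alone and by edgeR 0 without the B1/B2 term (6 at an unadjusted p under 0.05).

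Of 34 measured proliferation genes, 32 were tested and 4 rose, all parts of the DNA replication machinery: MCM3 (15.1 ± 4.05 to 51.6 ± 34 CPM, log2 fold change 1.68), MCM4 (1.87), MCM5 (1.53) and the sliding clamp PCNA (49.9 ± 14.0 to 133 ± 74.9 CPM, 1.32). Adjusted over the list alone, 12 were higher and 0 lower. The list was higher (median 0.73, camera adjusted p = 3.03e-10; adjusted p = 0.585 with an estimated correlation). edgeR called 0 members without wild-type replicate 2 or 3 or S34F replicate 3 (10, 7 and 8 at an unadjusted p under 0.05), 1 without wild-type replicate 1, 12 without S34F replicate 1 and 9 without S34F replicate 2, and DESeq2 called 2. By edgeR 0 were called without the B1/B2 term and in B1 alone (11 and 6 at an unadjusted p under 0.05), and 1 at equal depth and with 10 reads in every library.

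Of 25 measured genes of hypoxia and glycolysis, 17 were tested and edgeR called 0 (also adjusted over the list alone), with 5 at an unadjusted p under 0.05. The list was higher as a set (camera adjusted p = 0.000813; adjusted p = 0.585 with an estimated correlation). ADM, the gene of the vessel-dilating peptide adrenomedullin, had the smallest p (log2 fold change 1.05, edgeR adjusted p = 0.0925). Among 19 measured stable noncoding transcripts, 16 were tested and the snoRNA host genes SNHG8 (298 ± 143 to 102 ± 47.1 CPM, log2 fold change -1.59) and SNHG12 (-2.04) fell. Adjusted over the list alone, 6 of its members were lower and SNHG3 higher. The list was lower (camera adjusted p = 0.00396; adjusted p = 0.585 with an estimated correlation), except without wild-type replicate 2 (adjusted p = 0.0570). By edgeR 0 were called without wild-type replicate 2 or 3 or S34F replicate 3 (4, 5 and 5 at an unadjusted p under 0.05), and 5 and 4 were called without S34F replicate 1 and 2. It called 0 without the B1/B2 term and in B1 alone (5 at an unadjusted p under 0.05 in each), 1 at equal depth and with 10 reads in every library and 6 without a filter, and limma-voom called 1. The long noncoding RNA genes, a list drawn up after the data were seen, held 132 tested of 693 measured genes. LINP1 rose (log2 fold change 1.86) and 15 fell, with 4 higher and 28 lower adjusted over the list alone. That list was lower (camera adjusted p = 3.48e-06; adjusted p = 0.476 with an estimated correlation).

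The following lists were not called by camera, and the counts of members in them are from edgeR with Benjamini-Hochberg correction. U2AF1L4, a paralogue of the mutated gene, was the only called gene of 24 tested for splice-site recognition and fell from 45.1 ± 10.5 to 11.6 ± 5.47 CPM (camera adjusted p = 0.705). Among 17 tested basal epithelial markers, CAV1, the gene of the membrane protein caveolin 1, rose (97.6 ± 22.4 to 295 ± 38.5 CPM) and the laminin gene LAMB3 fell (2175 ± 240 to 841 ± 170 CPM; camera adjusted p = 0.331). KRT6B, a keratin gene with close paralogues, fell among 5 tested markers of squamous differentiation (camera adjusted p = 0.329). Of 13 tested genes named before as splicing targets of the mutation, UPP1 alone was called (camera adjusted p = 0.814). Of 1080 tested loci without a gene ID, 18 rose and 22 fell (camera adjusted p = 0.705). No member was called among 14 interferon response genes (camera adjusted p = 0.0564; 0.0476 with replicates as blocks, 0.00597 without S34F replicate 1 and 0.0191 without S34F replicate 3). The same held for 80 ribosomal protein genes (0.0630; 0.00775 without wild-type replicate 2 and 1.14e-07 without S34F replicate 2). It also held for 9 mesenchymal genes (0.0630; 0.0184 without wild-type replicate 1 and 0.00132 without S34F replicate 1) and 26 SR and hnRNP protein genes (0.169; 0.000659 without S34F replicate 1). It held as well for 14 epithelial junction genes (0.331), 11 polyadenylation factors (0.331), 17 autophagy genes (0.360), 2 mitochondrial genes (0.443), 33 translation factors (0.547) and 12 factors of nonsense-mediated decay (0.549). In these lists without a call, members at an unadjusted p under 0.05 by edgeR were 3 interferon response, 8 ribosomal protein, 2 mesenchymal, 6 SR and hnRNP, 3 junction, 1 polyadenylation, 3 autophagy, 0 mitochondrial, 5 translation and 1 decay gene. Adjusted over the list alone, edgeR called U2AF1L4 lower and SNRNP70 higher for splice-site recognition, and CAV1 and KRT5 higher and LAMB3 lower among basal markers. On the same terms it called KRT6B, UPP1 and MAP1LC3B lower and BUB3, SPARC and KRT19 higher in their lists, and 46 loci without a gene ID (22 higher, 24 lower). Too few blood-cell, secretory and ciliated markers were read for a test: 1, 1 and 0 of their genes passed the filter.

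At the level of single isoforms, the rises and falls of S34F cells include forms with no reads in 1 genotype. UPP1 isoforms with 9 and 10 exons that end at position 48148012 were read at 27.0 ± 5.65 and 18.1 ± 2.02 CPM in wild-type libraries and at 0 in S34F libraries. UPP1 also fell as a gene, from 5095 to 280 reads, so few S34F reads of these forms were to be looked for. Its isoform usage was not called by the Simes test (edgeR adjusted p = 0.116) but was by the gene-level F test and limma-voom. A form of FAM83A with 4 exons (16.8 ± 3.34 CPM), a form of FRMD4B with 3 exons (19.5 ± 5.95 CPM) and a form of SAA1 with 3 exons (14.4 ± 1.12 CPM), the gene of serum amyloid A1, also had 0 reads in S34F libraries. The annotated form of ALOX5AP with 5 exons fell from 108 ± 45.8 to 0.379 ± 0.656 CPM. A form with 1 exon on chromosome 22 (41684925 to 41685246) rose with a log2 fold change of 3.01, and an annotated form of GSTM3 with 2.96. Of 13961 isoforms, 595 passed (edgeR, Benjamini-Hochberg adjusted p of 0.05), 189 higher and 406 lower, and 364 of the 595 belong to genes that were called themselves. Each of the 12 isoforms chosen by rule was called whichever library was left out. At equal depth only 4 of these 12 were still tested, and with 10 reads in every library only 1, all of them called. The count of all called isoforms by edgeR was 3 without the B1/B2 term and 0 (932 at an unadjusted p under 0.05) with isolate 2 summed. It was 292 with DESeq2, 139 with 10 reads in every library, 184 in B1 alone and 196 at equal depth. Isoforms called were 322, 203 and 213 without wild-type replicate 1, 2 and 3, and 1339 and 256 without S34F replicate 2 and 3.

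Isoform usage, the share of a gene's reads on each of its isoforms, changed in few genes. The share of SAT1 reads on the annotated form ENST00000489394.1 fell from 16.1 ± 4.16% to 1.52 ± 0.737% in S34F cells (edgeR adjusted p = 4.62e-05), in the gene of the enzyme that acetylates spermidine and spermine. In SRSF3, a splicing factor gene of the SR family, the form ENST00000477442.2 fell from 19.9 ± 6.09% to 1.89 ± 1.01% and the form ENST00000373715.6-1 was at 48.1 ± 9.67% and 68.3 ± 3.67%. In BUB3, a gene of the spindle checkpoint, the form ENST00000368858.5-2 was at 15.7 ± 1.65% in wild-type and 34.5 ± 1.64% in S34F libraries. Forms of IFRD2 (1.64 ± 1.01% to 11.5 ± 1.01%), SNRPA1, which encodes a protein of the U2 particle (2.01 ± 1.2% to 12.2 ± 4.31%), and RWDD2B (3.96 ± 2.99% to 20.3 ± 7.27%) took larger shares. The form of FAM83A named above went from 8.85 ± 1.54% to 0, and the AGTRAP form ENST00000314340.5 was at 58.3 ± 4.08% and 69.7 ± 4.22%. TMEM40, HM13, TGFBI and S100A2 were called as well. Of 2276 genes with several isoforms, 14 passed (edgeR diffSpliceDGE with Simes p-values, Benjamini-Hochberg), 141 at an unadjusted p under 0.05. The count was 28 with the gene-level F test, 4 without a filter and 3 at equal depth, 5 when a change of 10 points was required and 1 without the B1/B2 term. It was 3, 5 and 0 without wild-type replicate 1, 2 and 3 and 4, 8 and 0 without S34F replicate 1, 2 and 3 (78 and 83 at an unadjusted p under 0.05 for the zeros). By edgeR it was 0 with 10 reads in every library, isolate 2 summed or B1 alone (33, 45 and 75 at an unadjusted p under 0.05). With a replicate block RWDD2B (edgeR adjusted p = 0.0846) and HM13 (0.0691) were not called. None of the 12 genes named here was called in every set that leaves out a library.

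Cassette exons, which an isoform holds or skips, were mostly skipped more in S34F cells where they were called. A SAT1 exon (chromosome X, 23802411 to 23802520) was in 33.1 ± 6.45% of wild-type and 4.53 ± 0.797% of S34F reads (edgeR adjusted p = 8.35e-40). An SRSF3 exon (chromosome 6, 36567598 to 36568053) fell from 27.4 ± 9.16% to 3.23 ± 1.36%. An exon of AGTRAP, the gene of a protein that binds the angiotensin receptor (chromosome 1, 11806184 to 11806280), fell from 16.2 ± 3.70% to 3.03 ± 0.570%, and an RWDD2B exon (chromosome 21, 30380082 to 30380444) from 87.8 ± 9.41% to 55.7 ± 12.5%. An exon of ITPA, whose enzyme removes inosine triphosphate (chromosome 20, 3193965 to 3194029), rose from 77.5 ± 1.73% to 94.3 ± 1.82%. Among alternative 3′ splice sites, use of the upstream site of BUB3 (chromosome 10, 124923336 against 124924563) fell from 61.6 ± 4.15% to 23.8 ± 2.68%. Some BUB3 isoforms end at 124923533, between these sites, so this form does not always hold a longer exon. It shares reads with the 3′ end change of BUB3 below. The longer form of PON2, a paraoxonase gene (chromosome 7, 95041055 to 95041091), fell from 80.1 ± 2.50% to 46.4 ± 7.36%. The longer form of SRP19, a gene of the signal recognition particle (chromosome 5, 112203069 to 112203101), rose from 13.9 ± 1.69% to 46.7 ± 7.05%, and those of EDF1 (20.8 ± 1.17% to 6.77 ± 3.85%) and SAP30BP (11.5 ± 3.83% to 2.69 ± 1.55%) fell.

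Alternative 5′ splice sites and retained introns changed in other genes as well as in these. The longer 5′ splice-site form fell in TMEM208 (18.2 ± 3.02% to 6.74 ± 2.31%), ELOVL1 (91.2 ± 0.934% to 78.7 ± 5.47%) and S100A2 (8.85 ± 1.12% to 3.91 ± 0.151%), and rose in UPP1 (chromosome 7, 48141467 to 48141579, 74.1 ± 2.49% to 95.5 ± 5.42%). The 5′ sites of SAT1 (35.6 ± 6.51% to 7.03 ± 0.818%) and RWDD2B (94.6 ± 4.84% to 79.3 ± 7.30%) share reads with their cassette exons. An intron was retained more in MIR205HG, the host gene of a microRNA (chromosome 1, 209602434 to 209602527, 58.2 ± 2.06% to 82.6 ± 5.18%). The called intron of SAT1 (chromosome X, 23802521 to 23803444) ranged from 21.1% to 71.6% in wild-type libraries and overlapped the S34F range.

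**Figure D2:**
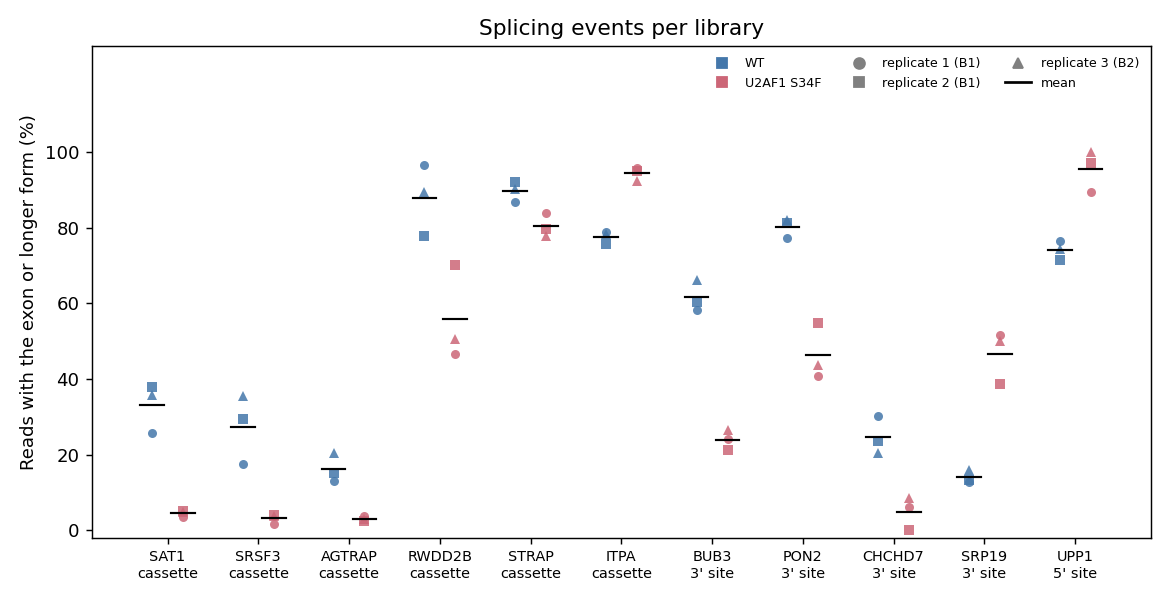
Percent of reads with the exon or the longer form of 11 splicing events in each library, for cassette exons, alternative 3′ splice sites and a 5′ splice site, with 1 point per library and the bar at the mean of 3 libraries. The SAT1 exon lies at 33.1% in wild-type and 4.53% in S34F libraries, and the 3′ site of SRP19 at 13.9% and 46.7%.

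Of 15625 tested events, 184 in 134 genes passed (edgeR on 2 counts per event and library, Benjamini-Hochberg adjusted p of 0.05), and 93 of them changed by at least 10 points. They were 83 of 7541 cassette exons (70 lower, 13 higher) and 43 of 3171 alternative 3′ splice sites (33 of the longer forms lower, 10 higher). They also were 24 of 2414 alternative 5′ splice sites (18 lower, 6 higher) and 34 of 2499 retained introns (11 lower, 23 higher). The share of lower inclusion among called cassette exons was 84.3% (exact 95% interval 74.7% to 91.4%), against 49.1% of all 7541 tested. Treating equal replicate numbers as pairs in a replicate block gave 107 events and limma on log odds 0 (1446 at an unadjusted p under 0.05). No B1/B2 term gave 35, isolate 2 summed 46, equal depth 34 and B1 alone 43. The count was 113, 93 and 43 without wild-type replicate 1, 2 and 3, and 117 and 39 without S34F replicate 1 and 3. Leaving out wild-type replicate 3 or S34F replicate 3 leaves a B2 library with no partner. The exon of RWDD2B (edgeR adjusted p = 0.370 and 0.351), its 5′ site (0.322 and 0.299), PON2 (0.0997 and 0.0986) and SAP30BP (0.255 and 0.266) were then not called, nor were TMEM208 (0.0939 and 0.105), ELOVL1 (0.0511 and 0.0569), S100A2 (0.0563 and 0.0539) and the UPP1 site (0.160 and 0.156). The UPP1 site was not called without S34F replicate 2 (0.0756) and ELOVL1 without S34F replicate 1 (0.0862) either.

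Of genes named before as splicing targets of the mutation, 11 had 77 tested events, and 7 events in BUB3, CHCHD7, UPP1 and STRAP were called. Besides the BUB3 site above, a BUB3 exon of 62 bases was in 8.27 ± 3.11% of wild-type and 2.04 ± 0.213% of S34F reads. In CHCHD7, the gene of a small mitochondrial protein (chromosome 8, 57128948 to 57128992), the longer 3′ splice-site form fell from 24.7 ± 4.98% to 4.93 ± 4.42% (edgeR adjusted p = 0.0232). An exon of STRAP, whose product binds serine-threonine kinase receptors (chromosome 12, 16036475 to 16036610), fell from 89.7 ± 2.72% to 80.5 ± 3.08% (edgeR adjusted p = 0.0464). A UPP1 exon fell from 9.96 ± 0.987% to 1.55 ± 1.36%. Not called were an exon of GNAS, the gene of a G protein subunit, at 45.5 ± 3.12% and 55.5 ± 4.47% (edgeR adjusted p = 0.411) and an exon of U2AF1 itself at 7.25 ± 0.962% and 4.65 ± 0.417% (0.553). No event was called in DEK, MED24, MACROH2A1, ITGB3BP, CEP164 or CTNNB1. With a replicate block, the edgeR adjusted p was 0.0534 for CHCHD7, 0.102 for STRAP and 0.0949 for the UPP1 exon. Without wild-type replicate 1, 2 and 3 it was 0.176, 0.0605 and 0.0962 for CHCHD7 and 0.0895, 0.112 and 0.304 for the UPP1 exon, and for STRAP it was 0.269 and 0.680 without wild-type replicate 2 and 3. Without S34F replicate 1, 2 and 3 it was 0.161, 0.191 and 0.0995 for CHCHD7, 0.0573, 0.172 and 0.688 for STRAP and 0.403, 0.107 and 0.296 for the UPP1 exon. The BUB3 exon was at 0.148 without wild-type replicate 3 and at 0.148 without S34F replicate 3.

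Mutations at this residue are known to change the choice of 3′ splice sites by the base just before the AG, so exons were grouped by that base where it could be read. Of the called cassette exons with T there, all 18 were skipped more in S34F cells, among them exons of RBM39, a splicing factor gene (42.9 ± 6.27% to 17.7 ± 0.472% inclusion), PABPC4, a poly(A)-binding protein gene (85.1 ± 3.82% to 57.9 ± 7.66%), CD151, a tetraspanin gene (67.3 ± 0.556% to 42.5 ± 3.73%), and RWDD2B. Of those with C, 8 of 14 were lower, including SAT1 and SRSF3, while the exons of DMKN (51.9 ± 1.39% to 74.1 ± 5.86%) and ERP29 (75.7 ± 4.47% to 89.8 ± 0.533%) rose. Both called exons with A, in ITPA and ILK, rose, and both with G, in AGTRAP and RNF181, fell. Over all tested exons with a known base, the mean change was -0.0149 points for 1443 exons with C, -1.50 points for 545 with T and 0.755 points for 103 with A. With the reads of all exons pooled per library, the comparison that has the libraries as replicates, the change of inclusion for C lay 0.808 points above that for T. The exact permutation p of that difference was 0.3 for 3 against 3 libraries, where 0.1 is the smallest possible, so this comparison could not pass 0.05. With each exon given equal weight, the mean change for C lay 1.49 points above that for T (2-sided permutation test over exons, p = 1e-05, the smallest that 100000 resamples can give), but exons are not independent replicates. Among exons with at least 20 reads in every library, 1203 with C and 431 with T, that difference was 0.935 points. The base was known for 2107 of the 7541 tested exons (27.9%), those whose upstream intron end is part of another annotated transcript, and 47 of the 83 called exons are not among them.

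**Figure D3:**
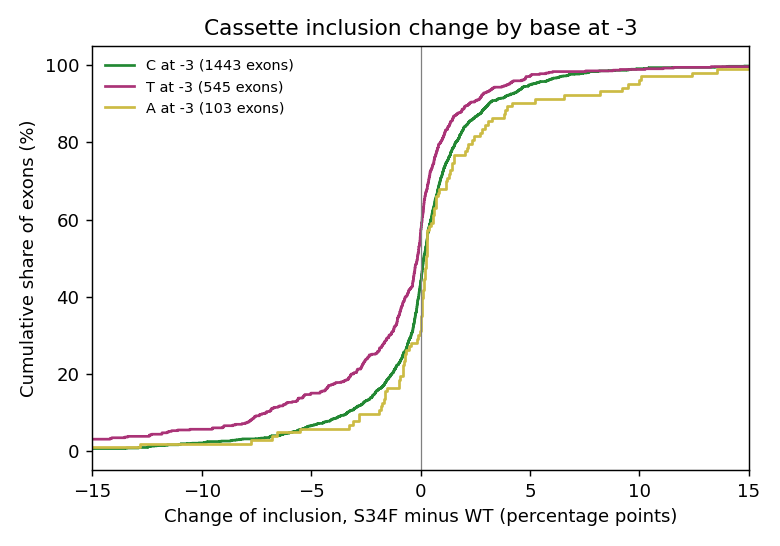
Cumulative share of tested cassette exons by change of inclusion (S34F minus wild type, percentage points, from -15 to 15), for exons with C (1443), T (545) and A (103) before the AG of the 3′ splice site. The curve for T lies to the left of that for C, with means of -1.50 and -0.0149 points.

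The choice between 3′ ends, where transcripts are cleaved and polyadenylated, differed in a small number of genes. In BUB3 the share of reads at the distal end (chromosome 10, 124924881, against 124923533) rose from 52.6 ± 4.90% to 85.3 ± 1.73% in S34F cells (edgeR adjusted p = 2.08e-16). The proximal end lies between the alternative 3′ splice sites of BUB3 above, so both results share reads and are not independent. In UFM1, the gene of a ubiquitin-like modifier, the distal share fell from 90.7 ± 2.04% to 66.0 ± 3.26%, in UPP1 from 37.9 ± 3.02% to 20.4 ± 4.52% and in RNF181 from 4.29 ± 0.578% to 1.23 ± 0.156%. In KRT5 it fell from 9.83 ± 3.84% to 3.37 ± 1.05%, but its distal end lies within the locus of the paralogue KRT6A. The called change of RPS15A (24.6 ± 25% and 36.6 ± 24.2%) overlapped between the genotypes. Of 2387 genes, 20 passed (edgeR on 2 counts, Benjamini-Hochberg), 10 with more and 10 with less of the distal end, and 8 of the 20 also had a called splicing event. A replicate block gave 8 genes and limma on log odds 0 (181 at an unadjusted p under 0.05). By edgeR, no B1/B2 term gave 1, isolate 2 summed 0 (116 at an unadjusted p under 0.05), 20 reads in every library 10, equal depth 2, a minimum change of 10 points 12 and B1 alone 5. The count was 13, 7 and 5 without wild-type replicate 1, 2 and 3 and 13 and 5 without S34F replicate 2 and 3. RPS15A turned direction without S34F replicate 3 (a change of -0.284 points) and was not called without wild-type replicate 1 (edgeR adjusted p = 0.205), without S34F replicate 1 (0.811) or with the block (0.0522). Calls ended without wild-type replicate 2 for KRT5 (0.0754) and UPP1 (0.0737) and replicate 3 for UFM1 (0.0657) and RNF181 (0.241). They also ended without S34F replicate 1 for RNF181 (0.0542), replicate 2 for UPP1 (0.0893) and replicate 3 for UFM1 (0.0719) and RNF181 (0.233).

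The make-up of the libraries was not called different between the genotypes by 2-sided exact permutation tests of 3 against 3 libraries. Their smallest possible p is 0.1, and they leave B1 and B2 out. Isoforms without an annotated transcript ID took 43.4 ± 5.32% of wild-type and 42.2 ± 4.72% of S34F reads (exact p = 0.5), and loci without a gene ID 12.5 ± 5.71% and 11.6 ± 5.13% (exact p = 0.6). Isoforms with a retained intron took 9.62 ± 0.936% and 9.96 ± 0.606% (exact p = 0.7). A read's isoform had 5.56 ± 0.162 and 5.66 ± 0.366 exons on average (exact p = 0.8) and a length of 1267 ± 156 and 1250 ± 140 bases (exact p = 0.9). The differences of S34F from wild type in B1 and B2 were -0.825 and -1.87 points for isoforms without a transcript ID, -0.575 and -1.54 points for loci without a gene ID, 0.240 and 0.544 points for retained introns, 0.123 and 0.0483 exons, and 4.56 and -62.6 bases. Both shares of reads without an ID were lower in S34F cells at each of replicate numbers 1, 2 and 3 (40.3, 40.4 and 49.5% against 39.5, 39.5 and 47.7% without a transcript ID, and 8.52, 9.86 and 19% against 8.22, 9 and 17.5% without a gene ID). Within B1 these numbers do not pair the libraries, and 3 pairs are too few for an exact p under 0.05. Leaving out a library unbalances B1 and B2, and the unpaired differences then turned direction. Without wild-type replicate 3 it was 1.90 points for isoforms without a transcript ID, 2.38 points for loci without a gene ID, -0.109 points for retained introns and 70.2 bases. Without S34F replicate 1 it was 0.178 and 0.775 points for the first 2 and 56.0 bases, and without S34F replicate 2 it was 0.198 and 0.385 points and -0.0896 exons.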

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

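The tests of depth, of blood cells and of isolates, that of nested introns, that of minor forms at lower inclusion and the comparison with other splits of the libraries were chosen after the results were seen; those of minor forms at inclusion over 50%, of the base before the AG and of unspliced RNA were not, though the route by which that base was read was. Groups of 3 libraries are too small for a test of single libraries far from the rest, and no difference between 2 contrasts and no data outside the main measurement came up.

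The first pattern is the fall of 8 inflammatory cytokine and chemokine genes in S34F cells, with a median log2 fold change of -3.93. Whether deeper wild-type libraries are the cause stays open. In libraries thinned to equal depth, all 8 stayed lower with a median log2 fold change of -4.27. Thinning draws from the same counts and leaves a gene's expected fold unchanged, so this could hardly have come out otherwise. By the criterion set first, at least 6 still called, the answer was open too, as 4 of the 5 still testable were called. The fold was taken after that. Blood cells in the wild-type cultures stay open: of 12 marker genes only 2 are in the table, CD68, not lower in S34F cells (65.2 CPM in wild-type and 78.7 CPM in S34F cells), and CD14, with 14 reads and 1 read, and their mean of 34.2 CPM is 9.99% of that of IL1B, at the bound of 10%. The genotype cannot be told apart from the culture state or origin of the isolates, since there are 2 isolates per genotype. An effect of the mutation itself is untested beyond that.

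The second pattern is the lower inclusion of 70 of 83 called cassette exons. After thinning to equal depth, 85.7% of 14 called exons were lower (exact interval 57.2% to 98.2%). All 34 events called after thinning were among the 184 called before, and thinning draws from the same counts. This share thus cannot decide whether depth is the cause. Minor forms found mainly in the deeper wild-type libraries would make exons with inclusion over 50% mostly higher in S34F cells, and of all 5703 such tested exons 42.6% were lower, but of the 39 called ones 69.2% were (52.4% to 83.0%), which argues against this source for them. For exons at lower inclusion it stays a candidate explanation, since 43 of 44 called and 69.2% of 1838 tested ones were lower (67.0% to 71.3%). Weaker use of 3′ splice sites with T before the AG is another candidate. With equal weight per exon the change of inclusion for C lay 1.49 points above that for T. With at least 20 reads in every library that difference was 0.935 points. The pooled comparison put first in the plan gave 0.808 points (exact permutation p = 0.3, where 0.1 is the smallest possible). Only 36 of the 83 exons have a known base, with C in SAT1 and SRSF3.

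The third pattern is that all 17 called retained introns with a change of at least 10 points were higher in S34F cells. Unspliced RNA or genomic DNA in the S34F libraries would raise most introns. Of 2499 tested introns 45.3% were higher (exact interval 43.4% to 47.3%), which argues against a rise of most introns. A smaller contribution stays open. Cassette exons at lower inclusion were mostly lower in S34F cells, and whether intron forms are shifted down in the same way was not tested. The 17 introns lie in 8 genes, 4 of them in MIR205HG, so nested introns of a few genes are a candidate explanation for their number. No biological explanation was tested for this pattern.

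The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and in each comparison 1 split, the real one, gave the highest count. The real split gave 228 genes, 595 isoforms, 14 genes in isoform usage, 184 events and 20 genes in 3′ ends, and the highest of the others 0, 0, 0, 2 and 9 (edgeR, Benjamini-Hochberg). The other splits that part the libraries of equal number for all 3 replicate numbers gave 0 genes, at most 2 events and 0 genes in 3′ ends. They place both genotypes in each group.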

How the results depend on the processing

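The tests on thinned libraries, the alternatives of the share of lower cassette exons, and the base tests with libraries left out or B1 and B2 apart, were added after the results were seen; the other alternatives were fixed before. Where a value moved, the cause was not tested, except that summing isolate 2, B1 alone, a left-out library, stricter filters and minimum changes leave fewer samples or features by construction. The main counts are 228 genes, 595 isoforms, 14 genes in isoform usage, 184 events, 20 genes in 3′ ends, 6 lists, 84.3% of called cassette exons lower and 1.49 points between the changes of exons with C and T. Thinned to equal depth, which leaves fewer reads, the counts by edgeR were 87 genes, 196 isoforms, 3 in usage, 34 events and 2 ends. B1 libraries alone gave 79, 184, 0 in usage (75 at an unadjusted p under 0.05), 43 and 5. Without the B1/B2 term they were 2, 3, 1, 35 and 1, and 92.9% of called cassette exons were lower. Summing the libraries of isolate 2 gave 0 genes, 0 isoforms, 0 in usage and 0 ends (287, 932, 45 and 116 at an unadjusted p under 0.05), 46 events and 95% of called cassette exons lower. The replicate block gave 107 events and 8 ends. It took called cassette exons from 83 to 51 and moved the counts of genes, isoforms, usage and lists by under 1.5 times, and of the lists it turned only the interferon list (0.0476). At least 10 reads in every library left 72 genes, 139 isoforms and 0 in usage (33 at an unadjusted p under 0.05), and at least 20 reads left 10 ends. With at least 10 reads the inflammatory median turned to 0.26 with 2 of its genes tested. That filter drops genes that fell to few S34F reads, such as CXCL1, CXCL2 and CXCL3. This turn thus does not bear on the fall of the called members. No filter gave 491 genes and 4 in usage. DESeq2 gave 292 isoforms, the F test 28 genes in usage, limma on log odds 0 events and 0 ends (1446 and 181 at an unadjusted p under 0.05). A change of at least 10 points left 5 in usage, 93 events and 12 ends. An estimated correlation left 0 lists (2 at an unadjusted p under 0.05) and fry 1. The 1.49 points weigh each exon equally. With at least 20 reads in every library they became 0.935 points. Pooled reads, put first in the plan, gave 0.808 points (exact permutation p = 0.3, where 0.1 is the smallest possible). With each library left out in turn the counts ran from 67 to 655 genes, 203 to 1339 isoforms, 0 to 8 in usage (78 and 83 at an unadjusted p under 0.05 where it was 0), 39 to 167 events, 5 to 16 ends and 6 to 9 lists. In the same sets 76.5% to 88.9% of called cassette exons were lower and C and T differed by 1.39 to 1.59 points. The RPS15A distal end turned from 12.1 to -0.284 points without S34F replicate 3 and was at 26.3 points without wild-type replicate 3. Of the named calls, 16 of 25 genes, 12 of 12 isoforms, 0 of 12 in usage, 14 of 29 events and 1 of 7 ends held in all 6 sets. The block kept 25 of 25 genes and 25 of 29 events, DESeq2 22 of the 23 genes it gave an adjusted p, limma-voom 24 of 25 genes. Among the named calls and list medians only RPS15A and, through that filter, the inflammatory median changed direction in any alternative. Each unpaired difference in library make-up did so with a library left out, which unbalances B1 and B2. Not called with all 6 libraries, BUB3 (0.0178) and ITGB3BP (0.0147) passed at gene level without S34F replicate 1.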

Other observations

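The test of event genes against gene-level calls was chosen after the results were seen, and so were the genes named in this part; these genes were not recomputed under the alternatives. Several genes of chaperones were higher in S34F cells by edgeR with Benjamini-Hochberg correction. HSPA8, which encodes a constitutive heat-shock protein, was at 123 ± 27.9 CPM in wild-type and 486 ± 217 CPM in S34F libraries (n = 3), the stress-induced HSPA1A at 5.86 ± 3.34 and 25.3 ± 8.39 CPM, and DNAJA1, a co-chaperone gene, at 23.6 ± 3.95 and 97.4 ± 68.2 CPM. Similar heat-shock genes can share reads. Genes of detoxifying enzymes besides GSTM3 and AKR1C3 were higher too: MGST1 (78.9 ± 13.8 and 165 ± 6.11 CPM), MGST3 (125 ± 31.7 and 289 ± 116 CPM) and ALDH3A2 (21.0 ± 6.16 and 61.1 ± 7.83 CPM). Neither set was tested as a group.

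Among genes that were lower, the tRNA synthetase gene CARS1 was at 135 ± 16.6 and 59.7 ± 16.4 CPM, SHMT2, of mitochondrial serine metabolism, at 333 ± 53.2 and 163 ± 39.8 CPM, and PCK2, which encodes a mitochondrial carboxykinase, at 80.6 ± 17.9 and 22.1 ± 7.89 CPM. The phosphatase gene DUSP1 was at 306 ± 103 and 59.0 ± 19.8 CPM, the receptor gene TNFRSF12A at 3134 ± 543 and 1194 ± 179 CPM, and G0S2, whose product inhibits a lipase of fat droplets, at 7112 ± 1689 and 2134 ± 667 CPM.

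A hypothesis tested here is that genes with a called splicing event also change in level. Of 134 such genes 5 were called at gene level, against 62 of 2797 other genes tested for both, an odds ratio of 1.71 (interval 0.527 to 4.31, Fisher's exact p = 0.232). The interval leaves both an excess and none open. The 5 are MGLL, SAA1, SNHG17, TNFRSF12A and UPP1.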
